A study of Mus musculus with 10 samples.

How the data were processed

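RNA from cumulus cells, mural granulosa cells and whole cumulus-oocyte complexes of mice was sequenced, and 10 libraries were analysed. Groups follow the labels: cumulus cells of C57BL/6 mice at 10 months (n = 3) and at 2 months (n = 3), mural granulosa cells of C57BL/6 mice at 2 months (n = 2), and 1 library each of BDF1 and DBA/2 complexes from mice aged 3 weeks. The labels' protocols name a culture medium with milrinone, a phosphodiesterase inhibitor, a kit for total RNA, and gonadotropin-primed mice as the source of mural cells. The authors deposited FPKM values for all libraries in 1 table, made with TopHat2 2.1.0 and Cufflinks 2.1.0 on mouse build mm9, per the submitters' processing notes. The gene annotation, the strandedness of the libraries, the read length and the read depth are not given in the sources used here. Cufflinks FPKM are likelihood estimates, so whole reads could not be recovered from their steps, and no interval for counting error is given. Depth limits the precision of low values by an unknown amount.

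The table held 23234 gene symbols, with 0 repeated symbols and 1 repeated header line, which was dropped. Of these symbols, 20841 matched a table of mouse gene names and 23020 a RefSeq table of symbols and synonyms. The reference at hand is of another build than mm9, so no coordinates are given. There were 3 genes listed at 0 in a library and at an FPKM of at least 20 in at least 8 of 10 libraries (Gm15698, H1foo and Padi6), of which none is a gene that every cell uses. Members of families with near-identical copies, such as ribosomal protein, histone and globin genes, and genes that overlap an antisense gene are uncertain, since reads can be assigned to either. Short Mir and Snor genes held 10.3 to 21.4% of a library's summed FPKM. Spearman correlations between replicates were 0.898 to 0.947 for cumulus cells at 2 months, 0.902 to 0.931 at 10 months and 0.948 for mural cells, across genes, which are not independent replicates.

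Values were set to log2(FPKM + 1), a scale on which fold changes understate the change of low genes. Genes with a mean FPKM of at least 1 over the 8 C57BL/6 libraries entered 1 linear model with a term per group (12412 genes, 5 residual degrees of freedom), fitted with limma 3.58.1 in R 4.3.3 with an intensity trend. Contrasts were 10-month against 2-month cumulus cells and mural against cumulus cells at 2 months. Adjusted p-values are two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 33 gene lists, 32 with at least 4 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The remaining list, of genes encoded in mitochondria, had 0 members in the table. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move 1 way on balance. The power of the test with an estimated correlation was not examined, for either contrast. The complexes have 1 library per strain, so no p-value is given. Their lists are described by the percentile of the median log2 ratio among 10000 random lists of the same size, matched on expression in 20 bins (seed 1).

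Groups, tests, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Per contrast and direction the rule names the 8 genes with the largest log2 fold change among those that passed, with a mean FPKM of at least 5 in the higher group and no overlap between groups. Where fewer than 5 passed, it names the 8 with the smallest p, as values that did not pass. From each list it takes up to 4 members with the smallest p. It adds Amh, Slc38a3, Npr2, Nppc, Lhcgr, Cyp11a1, Cyp19a1, Kitl, Cd34 and Star for mural against cumulus cells, and Cdkn1a, Cdkn2a, Amh, Fshr, Esr2 and Inhba for age. For the complexes it takes Gdf9, Bmp15, Zp3, Kit and Fgf8, 10 genes with the largest excess over the other libraries, and 8 per strain with the largest ratio among genes with an FPKM of at least 10. Symbols of predicted genes and Mir and Snor genes were left out. Not all genes the rule takes are reported here. Single genes named to describe the implied mural share in cumulus replicate 3 at 10 months were chosen after their values were seen.

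The model was tested on simulated data with 12412 genes per comparison. For age it recovered 46% of 100 genes changed by a log2 of 1 and 91% of 100 genes changed by 2, and called 8 of 12182 unchanged genes. For mural against cumulus cells it recovered 33% of 100 genes and 85% of 100 genes, and called 3. In both, a list of 30 genes shifted by a log2 of 0.5 was called and 0 of 29 unchanged lists were. The simulated noise was independent between genes, whereas the estimated correlation within the real lists reached 0.97 (oocyte genes) and was 0.53 for cell cycle genes. The simulation therefore does not show how often lists of correlated genes are called falsely. Alternatives fixed at that stage changed the pseudocount, the filter, the scaling between libraries, the variance model, the libraries in the fit, the replicate block, the treatment of repeated symbols and the list test, and left out each library in turn. Further alternatives, chosen after seeing the data, left out both libraries with uneven marker RNA, took the oocyte list as a covariate, left out 488 genes at least 4 times higher in the complexes, or left out Mir and Snor genes.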

Results

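RNA was sequenced from mouse ovarian follicle cells, and transcript levels were given as fragment numbers scaled by transcript length and by the mapped fragments of the library (FPKM) for 23234 gene symbols in 10 libraries. Cumulus cells, the granulosa cells that surround the oocyte, were taken from C57BL/6 mice aged 2 months (3 libraries) and 10 months (3 libraries). Mural granulosa cells, which line the follicle wall, came from C57BL/6 mice aged 2 months (2 libraries). Whole cumulus-oocyte complexes (COC) came from mice aged 3 weeks primed with the gonadotropin PMSG, with 1 library each from DBA/2 mice and from BDF1 mice, the first-generation cross of C57BL/6 and DBA/2. The FPKM of a library summed to between 470377 and 603460, and between 11373 and 12637 genes reached an FPKM of 1. Read depth was not given in the sources used here. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

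Marker lists of several cell types were compared between the libraries. Oocyte genes were uneven among replicates: Gdf9, a growth factor secreted by the oocyte, stood at 54.4, 0.647 and 261 FPKM in cumulus replicates 1, 2 and 3 at 2 months. It stood at 41.7 to 84.5 FPKM at 10 months, and at 30.6 and 3.07 FPKM in the mural libraries. Immune markers had a median log2(FPKM + 1) of 1.24, 1.60 and 2.06 at 10 months, against 0.06 to 0.41 in cumulus cells at 2 months and 0.89 and 1.84 in mural cells. Cumulus replicate 3 at 10 months stood apart in mural, epithelial, erythroid, theca and endothelial markers: its mural markers had a median of 5.58, against 3.76 and 4.07 in the other replicates, and its surface epithelium markers 3.33, against 0.28 and 1.63. Its erythroid markers had a median of 3.10, against 0.05 and 0.27, its theca and stroma markers 2.43, against 1.25 and 1.54, and its endothelial markers 1.71, against 0.29 and 0.67. Its Cyp11a1, which makes pregnenolone from cholesterol, stood at 773 FPKM, against 15.7 and 255 in the other replicates.

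**Figure D1:**
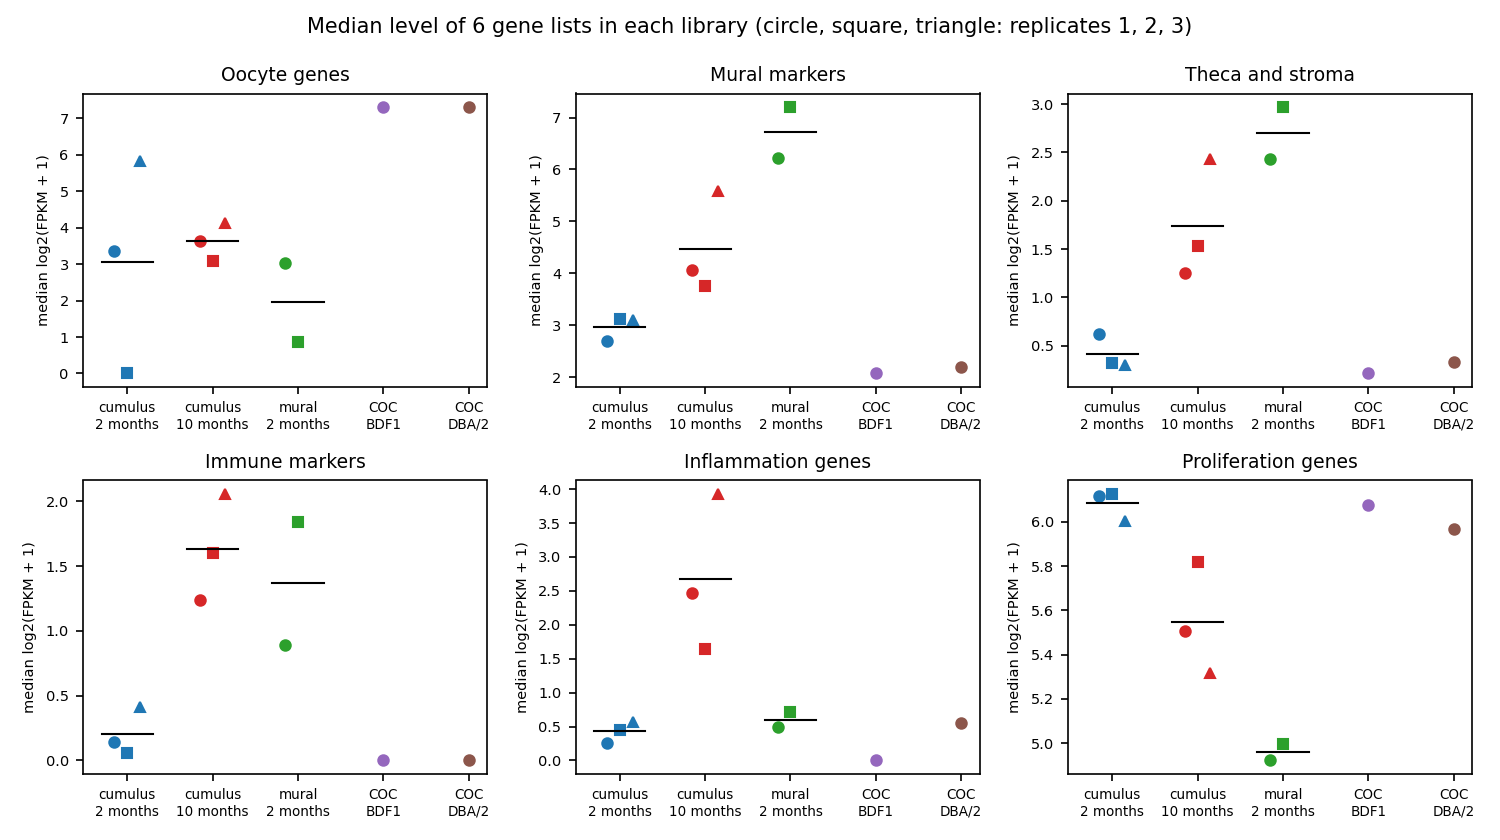
Median log2(FPKM + 1) of 6 gene lists (y axis) in each library by group (x axis); points are libraries, with shapes for replicates, and horizontal bars are group means. Oocyte genes lie between 0.00 and 5.81 among cumulus libraries at 2 months and at 7.31 and 7.30 in the complexes.

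Mural granulosa and cumulus cells of 2-month C57BL/6 mice were compared to describe how the follicle's granulosa compartments differ. The protocol names primed mice as the source of mural cells, and priming of the cumulus donors is not given in the sources used here, so this contrast is not separated from a possible difference in priming. Of 15 steroidogenic genes, 10 passed over all genes and 11 adjusted over the list alone as higher in mural cells, and 1 adjusted over the list alone as lower (camera adjusted p = 6.10e-06, adjusted p = 0.356 with an estimated correlation). Lhcgr, the receptor of luteinizing hormone, stood at 369.7 ± 127 FPKM in mural and 1.68 ± 0.307 in cumulus cells (SD, n = 2 and n = 3; log2 fold change 7.07 ± 1.05 SE, adjusted p = 0.00659, limma). Cyp11a1 stood at 1764 ± 985 against 13.9 ± 4.12 (log2 fold change 6.81, adjusted p = 0.0147). Star, which carries cholesterol into mitochondria, stood at 122 ± 69.0 against 1.79 ± 0.288 (log2 fold change 5.35, adjusted p = 0.0156). Cyp19a1, the aromatase that makes estradiol, stood at 341 ± 24.1 against 34.2 ± 5.11 (log2 fold change 3.28, adjusted p = 0.00182). Hsd3b1 stood at 4077 ± 745 against 204 ± 27.0 (log2 fold change 4.31, adjusted p = 0.00199). Nppc, which encodes the natriuretic peptide that holds oocytes in meiotic arrest, was also higher in mural cells, at 149 ± 2.48 against 29.7 ± 7.27 (log2 fold change 2.32, adjusted p = 0.00561). Its receptor Npr2 was higher in cumulus cells, at 95.0 ± 15.3 against 241 ± 34.4 (log2 fold change -1.33, adjusted p = 0.0137). Amh, anti-Mullerian hormone, was higher in cumulus cells, at 90.9 ± 75.8 against 369.9 ± 54.2 (log2 fold change -2.30, adjusted p = 0.0211). Kitl (34.8 ± 1.82 against 6.92 ± 1.24; log2 fold change 2.19, adjusted p = 0.0610) and Slc38a3, an amino acid transporter (31.5 ± 17.4 against 45.2 ± 11.3; log2 fold change -0.58, adjusted p = 0.397), did not pass.

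Of 12412 genes tested with limma, 2599 passed an adjusted p of 0.05, with 1203 higher and 1396 lower in mural cells. An unadjusted p under 0.05 was reached by 4563. A difference of at least 2-fold was seen in 777 of the higher and 543 of the lower genes. Beside Lhcgr, Cyp11a1, Star and Cd34 (54.5 ± 14.4 against 0.333 ± 0.296), the 8 genes with the largest differences in favour of mural cells were Sfrp4 (447 ± 286 against 2.57 ± 1.37), Comp, a cartilage matrix protein (125 ± 13.1 against 0.662 ± 0.0892), Prss35 (139.8 ± 64.9 against 1.49 ± 0.230) and Cst8 (123 ± 75.7 against 1.82 ± 0.995). In favour of cumulus cells they were Fosb (23.2 ± 26.3 against 365 ± 254), Fos (66.3 ± 56.4 against 684 ± 289), Egr2 (1.01 ± 1.23 against 26.9 ± 21.2), Otof (1.02 ± 0.606 against 21.9 ± 1.14), Tgoln2 (0.776 ± 0.324 against 16.6 ± 3.42), Kctd14 (25.9 ± 10.4 against 213 ± 26.9), Aqp8, an aquaporin (0.671 ± 0.532 against 12.2 ± 2.70), and Ndufa4l2 (3.67 ± 0.809 against 35.8 ± 6.74). Values are FPKM ± SD for mural (n = 2) against cumulus cells (n = 3). The count rested on single libraries: it was 99 without mural replicate 2, 800 without mural replicate 1, 1164 without cumulus replicate 2 and 1698 without cumulus replicate 1. Of 110 named genes that passed, 11 did so without mural replicate 2 and 66 without mural replicate 1. Genes higher in mural cells made up 46.3% of those that passed, and 68.9% when each library was rescaled to the same sum, which moved the median log2 fold change of all genes from -0.08 to 0.15.

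Cell cycle genes were lower in mural cells: 30 passed over all genes and 33 adjusted over the list alone, of 33 members, with a median log2 fold change of -1.02 (camera adjusted p = 1.84e-14, adjusted p = 0.370 with an estimated correlation). Mcm6, part of the replicative helicase, stood at 42.1 ± 0.746 against 108 ± 8.42 and Aurka, a mitotic kinase, at 18.4 ± 0.356 against 49.0 ± 2.97. Among 34 DNA repair genes, 17 passed over all genes and 21 adjusted over the list alone as lower (camera adjusted p = 5.86e-07, adjusted p = 0.356 with an estimated correlation). Exo1 was a member (3.38 ± 0.541 against 9.68 ± 0.488). Glycolysis genes were lower too: 14 passed over all genes and 15 adjusted over the list alone (with 1 higher), of 18 (camera adjusted p = 2.16e-06, adjusted p = 0.481 with an estimated correlation). Ldha, lactate dehydrogenase A, stood at 313 ± 12.6 against 1246 ± 161, Pgk1 at 191 ± 20.9 against 542 ± 16.0 and Pfkp, a phosphofructokinase, at 12.5 ± 0.801 against 61.6 ± 5.28. Amino acid and nucleotide supply genes had 8 members past the test over all genes and 10 adjusted over the list alone as lower, of 26 (camera adjusted p = 2.83e-04, adjusted p = 0.481 with an estimated correlation). Members included Shmt2 (30.0 ± 0.962 against 96.8 ± 13.8) and Slc7a5 (40.7 ± 1.08 against 91.9 ± 7.55). Among 26 immediate early genes, 12 passed over all genes and 15 adjusted over the list alone as lower, with a median of -1.90 (camera adjusted p = 1.83e-04, adjusted p = 0.590 with an estimated correlation). The list was uneven among replicates, with a median log2(FPKM + 1) of 3.79, 5.37 and 5.84 in cumulus replicates 1, 2 and 3. It was 4.01 and 3.45 in mural replicates 1 and 2, so cumulus replicate 1 lay below mural replicate 1. Ier2 and Jund were examples (Ier2 42.4 ± 15.0 against 180.3 ± 31.4, Jund 66.9 ± 15.6 against 195 ± 5.23). Ribosomal protein genes had a median of -0.65, with 15 members past the test over all genes and 29 adjusted over the list alone as lower, of 78 (camera adjusted p = 1.15e-10, adjusted p = 0.590 with an estimated correlation). Near-identical pseudogenes make single members of this list uncertain. For nuclear genes of oxidative phosphorylation, 0 passed over all genes and 0 adjusted over the list alone, of 55, with a median of -0.26 (camera adjusted p = 0.0202, adjusted p = 0.875 with an estimated correlation). It did not pass after quantile normalization (adjusted p = 0.799) or rescaling (0.137), or over genes with a mean FPKM of at least 5 (0.159). Nor did it pass without cumulus replicate 1 (0.162), cumulus replicate 2 (0.0690) or mural replicate 1 (0.362).

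Extracellular matrix genes were higher in mural cells: 22 passed over all genes and 27 adjusted over the list alone, of 37, with a median of 1.22 (camera adjusted p = 2.18e-12, adjusted p = 0.356 with an estimated correlation). Among them were Spock2, a proteoglycan (41.9 ± 1.25 against 8.62 ± 0.798), Mmp14, a membrane-bound matrix protease (50.9 ± 5.10 against 13.9 ± 2.75), and Timp2 (22.9 ± 0.814 against 5.03 ± 1.22). Of 10 mural markers 8 passed over all genes and 9 adjusted over the list alone as higher (camera adjusted p = 8.09e-07, adjusted p = 0.356 with an estimated correlation). The list of luteal genes shares several members with the steroidogenic list. It had 10 members past the test over all genes and 10 adjusted over the list alone as higher, and 2 over all genes and 2 adjusted over the list alone as lower, of 14 (camera adjusted p = 7.93e-05, adjusted p = 0.370 with an estimated correlation). Ptgfr, the prostaglandin F receptor, stood at 22.2 ± 18.0 against 0.108 ± 0.0183. In the granulosa identity list, 4 passed over all genes and 5 adjusted over the list alone as higher and 1 over all genes and 2 adjusted over the list alone as lower, of 16 (camera adjusted p = 0.0347, adjusted p = 0.590 with an estimated correlation). Nr5a2, a nuclear receptor, stood at 253 ± 6.495 against 104 ± 15.7 and Inha, the inhibin alpha subunit, at 9202 ± 892 against 3864 ± 1021. This list passed under 12 of 20 alternatives. It did not pass without cumulus replicate 3 (adjusted p = 0.128), mural replicate 1 (0.152) or replicate 3 of both cumulus groups (0.122). Nor did it with the replicate block (0.0809), library weights (0.0558), median centring (0.0522), no filter on low values (0.0824) or the oocyte list as covariate (0.0611). Markers of other cell types were also higher in the mural libraries. Theca and stroma markers had 10 members past the test over all genes and 10 adjusted over the list alone as higher, of 14 (camera adjusted p = 5.86e-07, adjusted p = 0.356 with an estimated correlation). Aldh1a1 stood at 224 ± 42.0 against 23.0 ± 1.89 and Acta2, smooth muscle actin, at 20.03 ± 7.28 against 3.12 ± 0.211. Endothelial markers had 7 members past the test over all genes and 8 adjusted over the list alone, of 8 (camera adjusted p = 8.40e-06, adjusted p = 0.370 with an estimated correlation). Eng stood at 8.55 ± 5.56 against 0.0204 ± 0.0353. Immune markers had 3 members past the test over all genes and 6 adjusted over the list alone, of 12 (camera adjusted p = 5.16e-04, adjusted p = 0.481 with an estimated correlation). Lyz2, lysozyme, stood at 14.3 ± 12.1 against 0.674 ± 0.483. Surface epithelium markers had 2 members past the test over all genes and 9 adjusted over the list alone (with 1 lower), of 11 (camera adjusted p = 0.00205, adjusted p = 0.590 with an estimated correlation). None of the 16 lists that passed did so with an estimated correlation, where the smallest adjusted p was 0.356. Mural markers, with a median log2 fold change of 3.79, were among them. The power of this setting was not tested, so failing it does not show that a list is unchanged. The other 16 lists, cumulus markers and oocyte genes among them, had camera adjusted p from 0.0905 to 0.965. Fry did not call immediate early (adjusted p = 0.0713), ribosomal protein (0.0620) or granulosa identity genes (0.0713). Immune (0.0617), surface epithelium (0.117) and nuclear oxidative phosphorylation genes (0.422) were not called by fry either. Cumulus markers were called by fry as lower in mural cells (0.0246). Oocyte genes passed as lower in mural cells without cumulus replicate 2 (adjusted p = 4.07e-07) or mural replicate 1 (0.0149). Without mural replicate 1 cumulus markers (0.0371) and cholesterol synthesis genes (0.0149) passed, and without mural replicate 2 erythroid genes did (0.0259). Interferon response genes passed as higher with the replicate block (adjusted p = 0.00972), library weights (0.0203), a fit of these groups alone (0.0142) or without replicate 3 of both cumulus groups (0.0255). The median, mean and test differed in sign for the ovulatory response, tricarboxylic acid cycle, antioxidant and ER stress lists, none of which passed.

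Cumulus cells of 10-month and 2-month C57BL/6 mice were compared to describe what differs with age. No single gene passed the test across all genes. With a preset correlation, gene lists of inflammation, immediate early response and extracellular matrix were higher and cell cycle genes lower at 10 months. Markers of immune cells, theca and stroma and surface epithelium were higher too, the last not in the list median of 10-month replicate 1. With an estimated correlation 0 of 32 lists passed (smallest adjusted p = 0.134). Fry called 5 lists: inflammation, immune, theca and stroma, and p53 and senescence as higher, and DNA repair as lower. It did not call immediate early (adjusted p = 0.147), extracellular matrix (0.0845), cell cycle (0.0721) or surface epithelium genes (0.147). The smallest p belonged to Apoe, which carries lipids in lipoproteins, at 46.9 ± 16.2 FPKM at 10 months and 7.69 ± 0.387 at 2 months (SD, n = 3 each; log2 fold change 2.40 ± 0.25 SE, adjusted p = 0.0869, limma). Mt2, a metal-binding metallothionein, stood at 110.4 ± 17.0 against 27.9 ± 6.01 (log2 fold change 1.96, adjusted p = 0.0869). Its relative Mt1 stood at 411 ± 21.1 against 200.4 ± 18.5 (log2 fold change 1.03, adjusted p = 0.116). Cxcl10, a chemokine, stood at 21.0 ± 10.2 against 0.960 ± 0.978 (log2 fold change 3.50, adjusted p = 0.152) and Ier3 at 178 ± 45.2 against 32.8 ± 14.4 (log2 fold change 2.48, adjusted p = 0.152). Spock2 stood at 24.5 ± 4.79 against 8.62 ± 0.798 (log2 fold change 1.39, adjusted p = 0.0869) and Sepp1, a selenoprotein, at 16.8 ± 5.26 against 4.77 ± 0.580 (log2 fold change 1.59, adjusted p = 0.129). Rassf2 had a lower mean at 10 months, at 16.0 ± 2.38 against 42.9 ± 6.88 (log2 fold change -1.37, adjusted p = 0.0869). In the mural libraries (n = 2), Apoe (58.2 FPKM), Spock2 (41.9), Sepp1 (42.8) and Rassf2 (17.8) lay nearer to the 10-month mean. Mt2 (40.3), Mt1 (161), Cxcl10 (0.515) and Ier3 (8.82) lay nearer to the 2-month mean. In each of these 8 genes, picked for their small p, every library of one age lay beyond every library of the other. The same held for 17.8% of all genes tested.

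**Figure D2:**
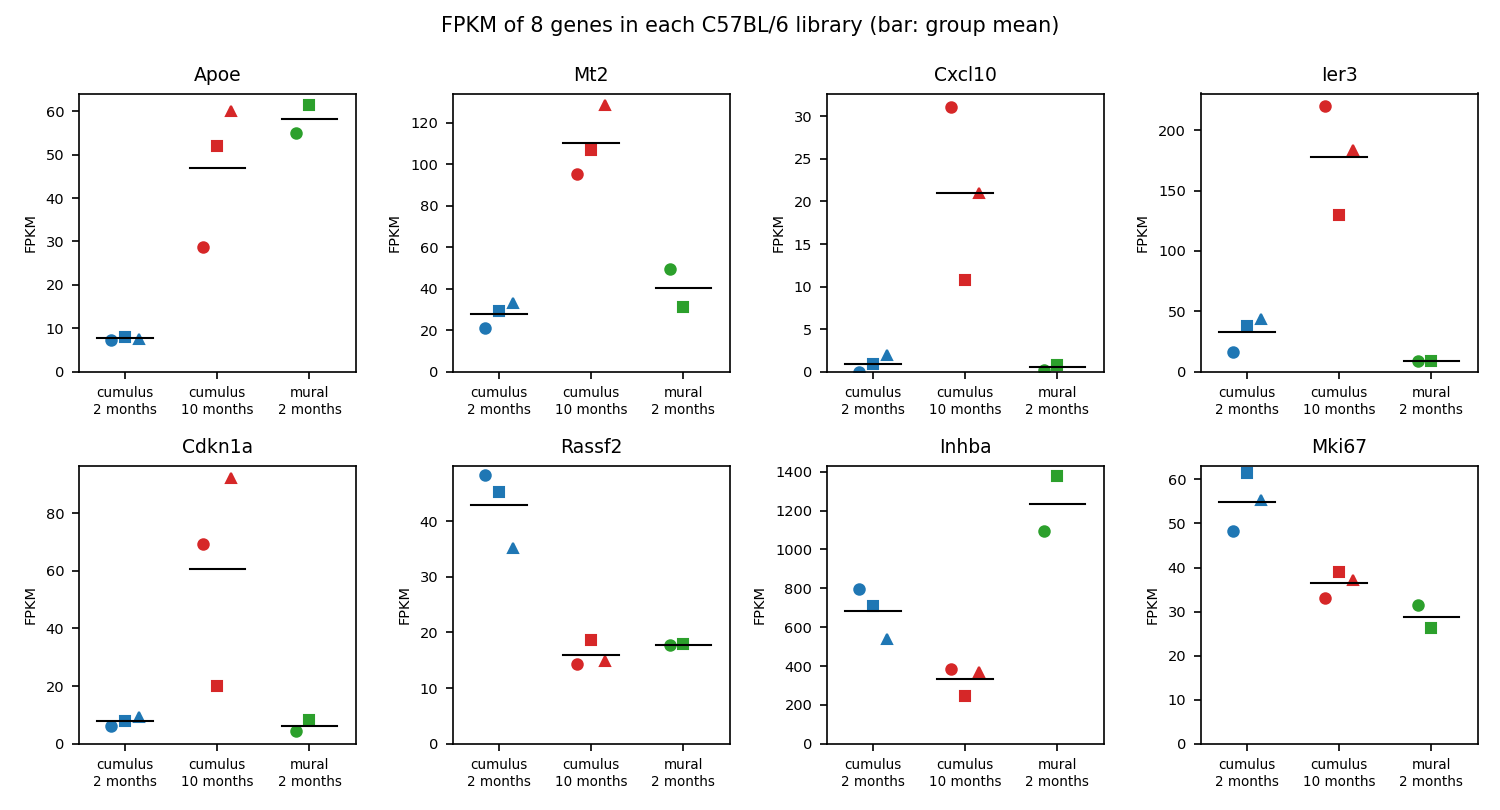
FPKM (y axis, linear) of 8 genes in each C57BL/6 library by group (x axis); points are libraries, with shapes for replicates, and bars are group means. Apoe lies between 28.8 and 60.0 FPKM at 10 months and between 7.35 and 8.11 at 2 months.

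Of 12412 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest was 0.0869. An unadjusted p under 0.05 was reached by 1727 genes (959 higher and 768 lower at 10 months), where 621 would be reached by chance with no effect. Genes are correlated, so this number is only a rough guide. Other splits of the same 6 libraries, which mix the ages, reached 196 to 2250. The libraries of both ages did not overlap in 17.8% of genes, and chance gives 10%. Leaving out cumulus replicate 2 at 10 months gave 245 genes (211 higher and 34 lower). Leaving out each other cumulus library in turn gave 3 to 6 genes, and library weights gave 69.

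Inflammation genes had higher means at 10 months in all 18 tested members, with a median log2 fold change of 2.02 (camera adjusted p = 5.96e-16, adjusted p = 0.260 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 15 did. Cxcl1 stood at 82.7 ± 16.8 against 15.1 ± 8.86, Cxcl2 at 10.0 ± 6.65 against 0.794 ± 0.617 and Il1b, interleukin 1 beta, at 6.20 ± 5.05 against 0.323 ± 0.131. All 12 immune markers had higher means too, with a median of 1.88 and 10 past the test adjusted over the list alone (camera adjusted p = 3.58e-11, adjusted p = 0.260 with an estimated correlation). Cd74, the invariant chain of antigen presentation, stood at 16.2 ± 12.9 against 1.09 ± 0.687 and Lyz2 at 15.0 ± 8.69 against 0.674 ± 0.483. Interferon response genes had 1 of 23 past the test adjusted over the list alone (camera adjusted p = 5.64e-05, adjusted p = 0.290 with an estimated correlation). This was H2-K1, a class I histocompatibility antigen (145 ± 14.2 against 85.5 ± 13.5). Immediate early genes had higher means in all 26 members, with a median of 1.11 and 4 adjusted over the list alone (camera adjusted p = 3.04e-09, adjusted p = 0.293 with an estimated correlation). Their median log2(FPKM + 1) was 6.01, 6.72 and 6.55 at 10 months, against 3.79, 5.37 and 5.84 in the uneven libraries at 2 months. The transcription factor Myc stood at 56.98 ± 18.7 against 15.3 ± 2.99 and Ctgf at 176 ± 87.9 against 28.8 ± 8.67. Genes of the ovulatory response had higher means in all 16 members, with a median of 1.73 and 11 adjusted over the list alone (camera adjusted p = 2.56e-10, adjusted p = 0.260 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, belongs to this list and to the inflammation list and stood at 19.1 ± 14.7 against 0.536 ± 0.4926.

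Genes of p53 and senescence had a median of 0.70 at 10 months, and 7 of 18 passed adjusted over the list alone (camera adjusted p = 6.10e-06, adjusted p = 0.134 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, stood at 60.6 ± 36.7 against 7.88 ± 1.58 (log2 fold change 2.56, adjusted p = 0.196), Gadd45a at 33.9 ± 14.3 against 7.85 ± 1.85 and Mdm2 at 28.8 ± 3.01 against 20.03 ± 2.09. Cdkn2a lay under the filter on low values, at 0.0951 ± 0.165 against 0.234 ± 0.404 FPKM. Antioxidant genes had a median of 0.21 with 0 of 33 past the test adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.340 with an estimated correlation). Hmox1, heme oxygenase 1, stood at 60.8 ± 14.4 against 32.1 ± 2.96. Heat shock genes had 2 of 15 adjusted over the list alone (camera adjusted p = 0.00661, adjusted p = 0.387 with an estimated correlation). These were the near-identical copies Hspa1a (13.6 ± 3.79 against 3.97 ± 0.819) and Hspa1b (14.2 ± 3.60 against 4.85 ± 0.993), whose reads can be split between them. Without cumulus replicate 2 at 10 months the heat shock list did not pass (adjusted p = 0.273).

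Cell cycle genes had lower means at 10 months in all 33 members, with a median log2 fold change of -0.54 (camera adjusted p = 5.96e-16, adjusted p = 0.281 with an estimated correlation). Over all genes 0 passed, and 17 passed adjusted over the list alone. Among them were Mki67 (36.4 ± 2.97 against 54.9 ± 6.62), Top2a, a DNA topoisomerase (87.2 ± 15.8 against 135 ± 12.4), Ccnd2, cyclin D2 (78.9 ± 9.91 against 122 ± 10.9), and Mcm4 (32.1 ± 4.26 against 45.9 ± 1.22). DNA repair genes had a median of -0.37 with 8 of 34 adjusted over the list alone (camera adjusted p = 1.59e-09, adjusted p = 0.260 with an estimated correlation). Msh6, a mismatch repair protein, stood at 22.9 ± 1.74 against 32.6 ± 2.78. Glycolysis genes had a median of -0.21 (camera adjusted p = 0.0455, adjusted p = 0.774 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of -0.14 (camera adjusted p = 0.0160, adjusted p = 0.877 with an estimated correlation). Of either list 0 members passed adjusted over the list alone. Neither list passed without cumulus replicate 3 at 10 months (adjusted p = 0.895 and 0.635, the latter in the opposite direction). Nor did either without cumulus replicate 1 at 2 months (0.171 and 0.383) or replicate 2 at 2 months (0.0762 and 0.0963), or over genes with a mean FPKM of at least 5 (0.0853 and 0.0560), without replicate 3 of both ages (0.339 and 0.0898) or with the oocyte list as covariate (0.0851 and 0.116). The glycolysis list was also lost with no filter on low values (0.0530), a fit of these groups alone (0.0562) and library weights (0.208), and passed under 12 of 21 alternatives. Inhba, an activin and inhibin subunit, stood at 334 ± 76.6 against 683 ± 131 (log2 fold change -1.04, adjusted p = 0.212), and Inhbb at 792 ± 266 against 1691 ± 539. Amh (590.1 ± 179 against 369.9 ± 54.2; log2 fold change 0.63, adjusted p = 0.586), the follicle stimulating hormone receptor Fshr (57.8 ± 16.9 against 76.5 ± 8.78; log2 fold change -0.43, adjusted p = 0.418) and the estrogen receptor Esr2 (54.5 ± 11.3 against 71.6 ± 5.68; log2 fold change -0.40, adjusted p = 0.453) did not pass.

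Extracellular matrix genes had a median of 0.52 at 10 months, with 12 of 37 past the test adjusted over the list alone (camera adjusted p = 1.35e-09, adjusted p = 0.281 with an estimated correlation). Itga5, a fibronectin receptor subunit, stood at 16.3 ± 10.2 against 1.63 ± 0.551, Mmp14 at 25.2 ± 2.81 against 13.9 ± 2.75 and Timp1 at 38.2 ± 22.3 against 9.36 ± 3.72. Markers of theca and stroma had a median of 1.32 with 7 of 14 adjusted over the list alone (camera adjusted p = 5.23e-08, adjusted p = 0.260 with an estimated correlation). Acta2 stood at 10.2 ± 4.18 against 3.12 ± 0.211 and Tagln at 5.78 ± 1.27 against 1.21 ± 0.458. Surface epithelium markers had a median of 1.34 (camera adjusted p = 1.62e-06, adjusted p = 0.293 with an estimated correlation), with 1 of 11 adjusted over the list alone and Krt18, a keratin, at 14.5 ± 10.3 against 2.69 ± 0.567. Their median log2(FPKM + 1) was 0.28, 1.63 and 3.33 in 10-month replicates 1, 2 and 3, against 0.32, 0 and 0.12 at 2 months. Endothelial markers had a median of 0.68 with 0 of 8 adjusted over the list alone (camera adjusted p = 0.00278, adjusted p = 0.405 with an estimated correlation), and mural markers 1.44 with 0 of 10 (camera adjusted p = 0.00217, adjusted p = 0.290 with an estimated correlation). Luteal genes had a median of 1.09 with 0 of 14 adjusted over the list alone (camera adjusted p = 8.41e-05, adjusted p = 0.290 with an estimated correlation) and steroidogenic genes 0.46 with 1 of 15 (camera adjusted p = 0.0109, adjusted p = 0.387 with an estimated correlation). Fdx1, the electron donor of steroid-making mitochondrial enzymes, stood at 344 ± 288 against 34.8 ± 3.62. The median of mural markers in the 10-month replicates was 4.07, 3.76 and 5.58. The steroidogenic list did not pass without cumulus replicate 2 at 10 months (adjusted p = 0.0807) or replicate 3 at 2 months (0.0932). With library weights neither the steroidogenic nor the mural list passed (adjusted p = 0.259 and 0.0918). Without replicate 3 of both ages the steroidogenic (0.240), mural (0.0706) and endothelial (0.0582) lists did not pass, nor did the endothelial list without replicate 3 at 10 months (0.0691). In all, 19 of 32 lists passed with the preset correlation (15 higher, 4 lower at 10 months) and 0 with an estimated one, where the smallest adjusted p was 0.134. The other 13 lists, oocyte genes, granulosa identity and cholesterol synthesis among them, had adjusted p from 0.205 to 0.991. The median, mean and test had differing signs for TGF-beta and inhibin genes and for granulosa identity. Without cumulus replicate 2 at 2 months, the library with the least oocyte RNA, the oocyte list passed as lower at 10 months (adjusted p = 3.53e-04). Without replicate 3 at 2 months, the library with the most, it passed as higher (3.02e-08). Ribosomal protein genes passed as higher without replicate 3 at 10 months (8.10e-09) or replicate 2 at 2 months (0.0299). With the replicate block the oocyte list (adjusted p = 0.0425) and the ribosomal protein list (0.0309) passed as higher. ER stress genes passed without replicate 3 at 10 months (0.0198) and cell contact genes without replicate 2 at 10 months (0.0450).

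**Figure D3:**
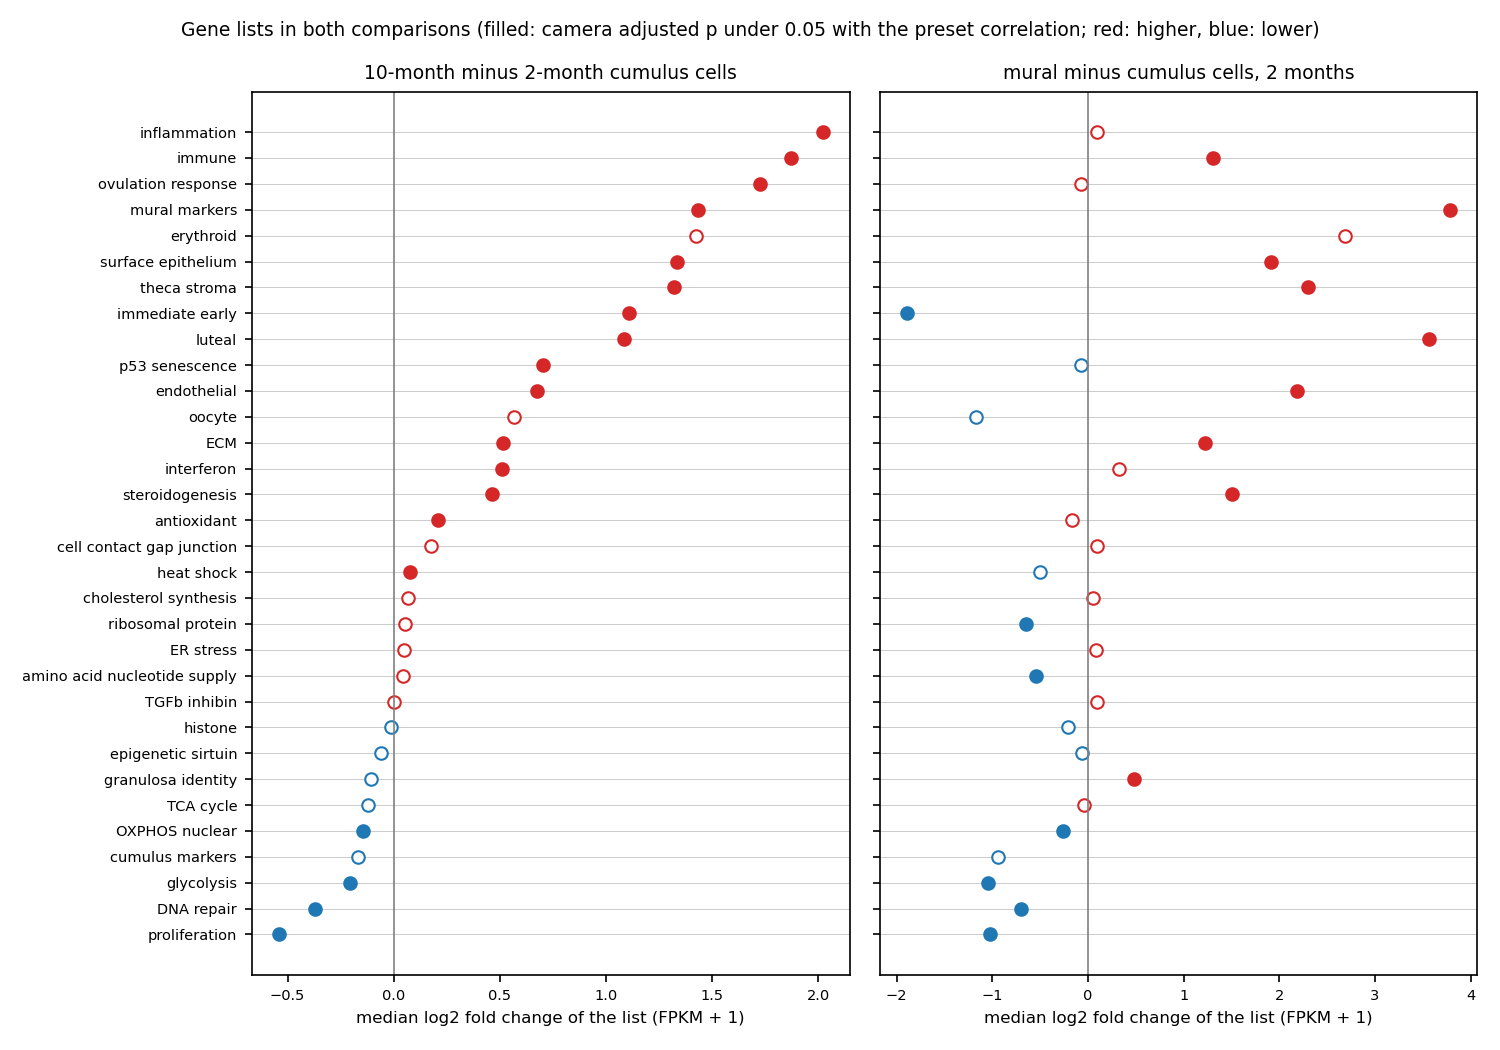
Median log2 fold change (x axis) of 32 gene lists (y axis) for age in cumulus cells and for mural against cumulus cells; filled points passed camera with the preset correlation, red is higher and blue lower. Proliferation lies at -0.54 and -1.02, and immediate early genes lie at 1.11 and -1.90.

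The COC libraries, 1 per strain with no replicate check, carried the oocyte's transcripts at high levels. Gdf9 stood at 951 FPKM in BDF1 and 894 in DBA/2. Zp3, a zona pellucida protein, stood at 480.3 FPKM in BDF1 and 438 in DBA/2. Bmp15, an oocyte growth factor, stood at 163 FPKM in BDF1 and 167 in DBA/2. The receptor kinase Kit stood at 26.1 FPKM in BDF1 and 14.9 in DBA/2 and Fgf8, a fibroblast growth factor, at 5.73 FPKM in BDF1 and 16.2 in DBA/2. Of 31 oocyte genes, 31 in BDF1 and 31 in DBA/2 exceeded their mean in 2-month cumulus cells. Their median log2 ratio was 3.96 for BDF1 and 3.98 for DBA/2, at percentiles 100 and 100 among 10000 random lists matched on expression. The size of this ratio rests on uneven cumulus libraries. Their median log2(FPKM + 1) of oocyte genes was 3.36, 0 and 5.81 in replicates 1, 2 and 3. Of 12454 genes, 422 were at least 4-fold above the cumulus mean in both complexes and 103 at least 4-fold below. Genes with the largest excess over all 8 C57BL/6 libraries included Serpina3a (103 FPKM in BDF1 and 240.4 in DBA/2), Bfsp1, a lens filament protein (18.8 FPKM in BDF1 and 43.9 in DBA/2), Pnpla3 (13.7 FPKM in BDF1 and 31.8 in DBA/2), Gtdc1 (182 FPKM in BDF1 and 199.6 in DBA/2) and Efemp1 (37.0 FPKM in BDF1 and 85.3 in DBA/2). Immediate early genes had a median log2 ratio to 2-month cumulus cells of -1.49 in BDF1 and -2.13 in DBA/2 complexes. Cholesterol synthesis genes had -0.67 and -0.75, and all of these ratios lay at percentile 0. The median log2(FPKM + 1) of immediate early genes was 4.09 in BDF1 and 3.22 in DBA/2, and 3.79 in 2-month cumulus replicate 1. Strain, age and the presence of the oocyte all differ between these complexes and the cumulus cells, and the titles name priming for the complexes alone.

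The complexes of both strains had a Spearman correlation of 0.941 across 12671 genes, which are not independent replicates. Among 7828 genes that reached an FPKM of 10 in either, 68 differed by at least 4-fold, with 43 higher in BDF1 and 25 higher in DBA/2 complexes. The immediate early gene Fosb stood at 56.1 FPKM in BDF1 and 2.96 in DBA/2 and Wfdc10 at 53.2 FPKM in BDF1 and 3.19 in DBA/2. Higher in DBA/2 were Serpina5 (9.38 FPKM in BDF1 and 58.2 in DBA/2), the transcription factor Klf1 (6.60 FPKM in BDF1 and 36.1 in DBA/2) and Penk, which encodes enkephalins (5.95 FPKM in BDF1 and 31.7 in DBA/2). Amh stood at 437 FPKM in BDF1 and 44.6 in DBA/2, and was singled out here after its values were seen. Art4 and Fam25c were listed at 0 in the DBA/2 library and at 16.5 and 24.4 FPKM in the BDF1 library. The median log2 ratio of BDF1 over DBA/2 was -0.00240 for oocyte genes, at percentile 24.4 among matched random lists. With 1 library per strain, BDF1 had the higher level of most histone genes (0.70, percentile 100, 30 of 34 members), cell cycle genes (0.29, percentile 100, 27 of 33 members) and ribosomal protein genes (0.15, percentile 99.99, 66 of 78 members). The same held for immediate early genes (0.30, percentile 99.78, 17 of 22 members) and DNA repair genes (0.22, percentile 99.76, 24 of 34 members). DBA/2 had the higher level of most luteal genes (-0.52, percentile 0.05, 10 of 12 members) and steroidogenic genes (-0.25, percentile 0.36, 10 of 14 members). TGF-beta and inhibin genes were split, with 12 members higher in BDF1 and 15 in DBA/2 (-0.21, percentile 0.17). Histone genes include near-identical copies whose reads can be split between them. Mir and Snor genes held 14.1% of the summed FPKM in the BDF1 library and 10.3% in the DBA/2 library. With 1 library each, a difference between strains is not separated from one between library preparations. Rescaling each library to the same sum raised the number of 4-fold differences from 68 to 103.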

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

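The runs without both libraries of uneven marker RNA, with the oocyte covariate, without complex-high genes and without Mir and Snor genes were chosen only after the results were seen. With limma, 0 genes passed for age, as under each alternative other than library weights (69), leaving out 1 library (3 to 245) and leaving out cumulus replicate 3 of both ages (7). For mural against cumulus cells 2599 genes passed, with library weights 5425, of which 2598 were shared. Leaving out 1 library gave 99 to 1850 genes, of which 88 and 1751 were shared. The arm with 1 library is then assumed to vary like the other groups. The share of higher genes was 55.4% after median centring. With an estimated correlation 0 lists passed for age and 0 for mural cells, and fry called 5 and 11. The other alternatives called 14 to 21 and 12 to 17 lists. For age, the nuclear oxidative phosphorylation list had adjusted p from 4.70e-05 to 0.635 with 1 library left out, the highest without 10-month replicate 3, where its direction reversed. The oocyte list ran from 3.02e-08 to 0.773 and passed in the opposite direction (3.53e-04) without 2-month replicate 2. The ribosomal protein list passed as higher for age after quantile normalization (adjusted p = 4.19e-05) and rescaling (0.0121). The cause was not tested. Over all settings, named genes gave 253 lost and 76 gained calls for mural cells and 50 gained for age, and lists 36 lost and 14 gained, and 56 and 14 for age, beside 2 in which the direction reversed (1 lost and 1 gained). A value called in neither setting changed sign 66 times. With the replicate block 0 genes and 21 lists passed for age and 3361 and 16 for mural cells. Deviations of libraries with 1 number correlated at -0.0517 to 0.214, not all over 0.1, so they were taken to share only a number. Whether cumulus and mural cells of 1 number came from the same animals is not given. Rescaling, which also raised values against the fixed FPKM floor of 10, moved the complexes' 4-fold differences to 103. Keeping repeated symbols apart changed nothing, since there were 0. Read depth is unknown and limits low genes most.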

Other observations

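The tests of somatic expression of oocyte genes, of the mural difference in immediate early genes, of the oocyte covariate, of 1 mural share, of single abundant mural genes and of the shared covariance were chosen only after the results were seen. Lists that did not pass between mural and cumulus cells held members that moved apart (FPKM ± SD, mural n = 2 against cumulus n = 3, limma). Among antioxidant genes 7 of 33 were higher and 2 lower in mural cells over all genes, and 7 and 2 adjusted over the list alone. Sod3, the extracellular superoxide dismutase, stood at 18.8 ± 2.15 against 0.599 ± 0.601 (log2 fold change 3.69, adjusted p = 0.00491) and Gsta4, a glutathione transferase, at 219.8 ± 18.4 against 30.4 ± 2.94 (log2 fold change 2.82, adjusted p = 0.00577). Heat shock genes had 7 of 15 lower over all genes and 7 lower and 2 higher adjusted over the list alone. The chaperone Hsp90aa1 was 1 of them (137 ± 6.82 against 318 ± 49.9; log2 fold change -1.20, adjusted p = 0.00761). Of cell contact genes 5 of 19 were higher and 2 lower over all genes, in the same numbers adjusted over the list alone. The adhesion molecule Pvrl2 stood at 22.6 ± 6.12 against 3.04 ± 1.08 (log2 fold change 2.56, adjusted p = 0.00616), F11r, of tight junctions, at 34.1 ± 1.82 against 4.39 ± 1.03 (log2 fold change 2.72, adjusted p = 0.00981), and Myo10, a myosin of cell protrusions, at 16.1 ± 1.22 against 44.0 ± 2.19 (log2 fold change -1.40, adjusted p = 0.00199). Smad7, an inhibitor of TGF-beta signalling, was lower in mural cells (3.56 ± 1.12 against 24.6 ± 6.00; log2 fold change -2.49, adjusted p = 0.00757), as was Dnmt1, the maintenance DNA methyltransferase (28.4 ± 3.65 against 73.0 ± 27.9; log2 fold change -1.27, adjusted p = 0.0209). Alas2, which starts heme synthesis in red cells, was higher in cumulus cells (1.77 ± 0.840 against 15.1 ± 1.61; log2 fold change -2.57, adjusted p = 0.00577), whereas the globin gene Hba-a1, which has a near-identical copy, was higher in mural cells (53.8 ± 10.6 against 1.31 ± 1.18; log2 fold change 4.72, adjusted p = 0.0303). Without mural replicate 2, 11 of 110 named genes passed.

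Between ages, lists that did not pass also held members with means on either side (10 months against 2 months, n = 3 each, limma). Among ER stress genes, Atf4, a transcription factor of the stress response, stood at 337 ± 79.8 against 191 ± 43.7 (log2 fold change 0.82, adjusted p = 0.238), and Sel1l, of the degradation machinery of the endoplasmic reticulum, at 35.0 ± 0.623 against 52.1 ± 5.397 (log2 fold change -0.56, adjusted p = 0.197). Cell contact genes had 2 higher and 2 lower adjusted over the list alone and 0 over all genes, with F11r at 19.9 ± 14.6 against 4.39 ± 1.03 and Myo10 at 31.9 ± 1.69 against 44.0 ± 2.19. Grem1, a BMP antagonist of the TGF-beta and inhibin list, stood at 32.3 ± 7.23 against 60.7 ± 13.4 (log2 fold change -0.89, adjusted p = 0.225).

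The 6 cumulus libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes, with 3 as the highest of the others. Any split reaches a count of 0, as all 10 do, so the gene count decides nothing here. The real split gave 19 lists, with 18 as the highest of the others, and 1 split, the real one, gave as many. At an unadjusted p under 0.05 the real split gave 1727 genes, and 2250 were given by the split that sets 10-month replicates 1 and 3 and 2-month replicate 3 apart.

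Over 26 oocyte genes, the median share of the complexes' level was 7.37, 0 and 37.9% in cumulus replicates 1, 2 and 3 at 2 months, 4.74 to 11.3% at 10 months, and 4.75 and 0.503% in mural replicates 1 and 2. Expression by the somatic cells themselves is argued against by the spread within 1 group, where the highest median oocyte FPKM + 1 at 2 months was 56.3 times the lowest. Oocyte RNA carried into the libraries may be the source, since at least 84% of 75 other genes, picked as high in both complexes and near absent from cumulus replicate 2 at 2 months, lay within 2-fold of the oocyte list's share in each of 6 libraries with a share over 1%. The ratio of the 75th to the 25th percentile of the shares reached 2.08, between the bounds set for and against carry-over, so that test leaves it open. Whether whole oocytes or free RNA was carried over was not tested.

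For the list changes between ages, mural cells like those of the 2-month mural libraries are argued against for immediate early and cell cycle genes. The median log2 fold change of immediate early genes was -1.90 in mural against cumulus cells (camera adjusted p = 1.83e-04, adjusted p = 0.590 with an estimated correlation) and 1.11 with age. For cell cycle genes, mural values mixed in at the libraries' mean mural share gave -0.13, against -0.54 observed. No mural cells of 10-month mice were sequenced, so mural cells in another state stay open for both lists. The immediate early median was 4.01 and 3.45 in the mural and 6.01 to 6.72 in the 10-month libraries. Cumulus replicate 1 at 2 months lay at 3.79, below mural replicate 1. Uneven oocyte RNA stays open, since the oocyte covariate cannot decide. The covariate was a median log2 level, whereas carried RNA would add in proportion to its share. That share was 0 and 37.9% in replicates 2 and 3 at 2 months, and 4.74 to 11.3% at 10 months. With the covariate 17 of 19 lists also passed. The other calls ended, for a reason not tested: the median log2 fold change of glycolysis genes (adjusted p = 0.0851 with the covariate) was -0.21 (quartiles -0.34 and -0.11) before and -0.22 (quartiles -0.30 and -0.09) after, and that of nuclear oxidative phosphorylation genes (0.116) -0.14 (quartiles -0.21 and -0.04) and -0.11 (quartiles -0.16 and 0.00734). Immune cells as a source of inflammation transcripts remain open: the 10-month library highest in inflammation genes ranked 3 of 3 (highest) in immune markers, but the others stood in opposite order (median log2(FPKM + 1) of immune markers 1.24 and 1.60 and of inflammation genes 2.46 and 1.64 in replicates 1 and 2), mural replicate 2 had 1.84 and 0.71, and 3 libraries are too few to decide. Age itself, untested, and differences in collection between ages, which the labels do not give, also stay open.

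Over 55 abundant mural genes, cumulus replicate 3 at 10 months had a median share of the mural level of 37.1%, against 3.38 and 10.4% in replicates 1 and 2. Of these genes, 10 lay below what 0.5 times the median share would give from the lowest cumulus and the lowest mural library. The bound against mural cells like those of the 2-month mural libraries was 10. It was set after the values were seen and equals the count, so this test cannot decide. Some lay far below, as Cyp19a1 (share 4.10%) and Nppc (16.1 FPKM, against 44.6 needed), and others less so, as Hsd3b1 (757 FPKM, against 809 needed). The ratio of the 75th to the 25th percentile of the shares was 2.90, between the bounds set for and against 1 share. A shared change toward the mural profile is a candidate explanation that stays undecided. The covariance of age and mural fold changes across genes was 0.241 (0.181 without this library). Over 100 simulations of unchanged groups with the same controls it had a mean of 0.0832 and a highest of 0.105. A higher covariance cannot tell a change in the cells from mural RNA in the libraries. The correlation of 0.454 lay near the simulated 0.446. The simulations took mural cells as unchanged too, where 2599 genes passed, so this correlation decides nothing. Mural cells like those of the 2-month libraries or in another state, age and handling stay open.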
